A study of Mus musculus with 4 samples.

How the data were processed

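RNA from 4 Wrn mutant and 4 wild-type mouse livers was hybridised in pairs to 4 two-colour Agilent arrays, with the mutant in Cy3 on 2 arrays and in Cy5 on the other 2, per the labels. The labels call the pairs independent biological replicates. The pairing is part of each array, so the ratio is the unit of analysis.

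The authors deposited 1 log2 ratio per probe and array, with medians of 0.00371, 0.00375, 0.00987 and 0.0182 for pairs 1 to 4. They also deposited a table with a log2 fold change, a p-value and an average log2 intensity per gene, per the file headers. The submitters' processing notes name limma. Its version, the background correction, the normalization within arrays, the filters and the way 1 probe per gene was chosen are not given in the sources used here. The deposited p-values followed the fit without a dye term (correlation of log10 p of 1.00 across genes, against 0.941 with the term). Which genotype is the numerator is not stated. All 4 columns were taken as 1 direction. Their mean correlated with the authors' deposited fold change at 0.985, against 0.164 after turning the arrays of 1 orientation. That fold change is the mean of the same 4 arrays for most genes, so the correlation shows how the authors averaged. It does not by itself show that the swapped arrays had been turned to 1 direction.

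Of 41174 probes, 35280 had 4 values, 4958 had 3, and 936 had fewer and were not tested. Missing values could hide dim probes: named probes with 4 values had a median average intensity of 6.79, and those with fewer had 5.44. The authors' table names 20909 probes, each with 1 symbol and each gene with 1 probe, so the planned mean over a gene's probes was that probe's value. The other 20265 probes are unnamed here but stayed in the test. Of 17813 named accessions, 17284 matched the reference table of assembly GRCm38.p6, used for names only, and 2713 symbols were updated. For 24 probes the printed symbol is the current name of another gene than the accession's. Lists were therefore matched by accession first, a rule set after the files were seen, and 1092 of 1131 list memberships were found, 33 of them through the updated symbol alone.

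Analyses ran in R 4.3.3 with limma 3.58.1. Each probe with at least 3 values was fitted with lmFit and eBayes on genotype plus a dye term, which left 2 residual degrees of freedom, with Benjamini-Hochberg adjustment over 40238 probes at 0.05. The threshold, the design, the lists and most alternatives were set before the data were examined. In 200 simulated changed probes among 40238, recovery at 1, 2, 4 and 6 log2 units was 0%, 2%, 48% and 78%, with 4 false calls among 68. These 68 calls themselves eased the adjusted threshold, so recovery would be lower where fewer probes change that much. The median standard error of a log2 ratio was 0.21. Signal over background was not analysed here.

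The 32 gene lists and 16 cell type marker lists were tested on 17686 genes with 4 values, using camera with a preset correlation of 0.01, camera with an estimated correlation, and fry, adjusted over all 48 lists. In simulated independent genes both lists shifted by 0.5 were called, and 0 others. Genes of the lists here were not independent, with an estimated correlation of 0.70 for Kupffer cell markers. The simulation therefore does not measure how often lists are falsely called in these data. With the preset correlation 11 lists passed, 5 higher and 6 lower. With an estimated correlation 0 passed (lowest adjusted p = 0.786), and with fry 0 passed in 1 direction (lowest adjusted p = 0.142) and 25 for change in either direction. Correlation alone does not account for the loss with camera. Cholangiocyte markers had an estimated correlation of -0.0059, below the preset, yet their unadjusted camera p went from 0.0027 to 0.088.

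Genes named in the text had 1 symbol and the same direction on all 4 arrays. Because 0 passed, the 10 per direction with the smallest unadjusted p under 0.01 and an absolute mean log2 ratio over 0.5 were named as values that did not pass, with Wrn. For each list that passed, up to 4 members with the smallest unadjusted p in its direction were also named, whether or not all 4 pairs went the same way. Some members that this rule names are not reported here. Exceptions are marked as chosen after their values were seen. Mean ± SD is over the 4 pairs.

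Alternatives were centring or scaling each array, leaving out each pair, array weights, robust eBayes, named probes only, an intensity filter, no dye term, the opposite reading of the dye swap, other thresholds, an unmoderated test, and other list tests. Scaling used median absolute values, because limma's normalizeBetweenArrays, the function first chosen, matches medians when given a plain matrix, and these lie near 0 for ratios. Testing by gene equalled the named-probe fit. Per-array values other than these, the choice among several probes per gene, and robust eBayes for lists had nothing to act on and were not run.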

Results

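Gene expression was compared between livers of Wrn mutant mice and wild-type mice. Wrn encodes a RecQ DNA helicase, and loss of its human counterpart causes Werner syndrome, a disorder of premature ageing. All animals were C57Bl/6 males aged 3 months, fed freely and kept on a reversed cycle of 12 h light and 12 h dark. Each of the 4 two-colour arrays carried RNA of 1 mutant liver and 1 wild-type liver, giving 4 independent pairs. The mutant RNA was labelled with Cy3 in pairs 1 and 2 and with Cy5 in pairs 3 and 4. Of 41174 probes, pairs 1 to 4 had values for 37627, 40032, 40104 and 39979. The number of arrays limits the precision of every value below.

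The ratios are given as mutant over wild type. That direction is likely rather than stated, and rests on the sample titles and the name of the authors' deposited table, which both put the mutant first. For 17537 of 17686 genes with 4 values, the fold change in the authors' deposited table is the mean of the 4 arrays with 1 common sign. For the other 149 it differs. The authors thus averaged the arrays as if all ran the same way, but neither arrays nor table state the numerator. If the numerator were wild type, every sign below would turn.

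The comparison asked which liver transcripts differed between the genotypes at 3 months. The probe for Wrn itself read higher in the mutant in 4 of 4 pairs, with log2 ratios of 1.77, 0.91, 1.12 and 1.37 and a mean of 1.29 ± 0.37 (SD, n = 4), or 2.45-fold. This did not pass the test over all probes (adjusted p = 0.736). An exact two-sided sign-flip test of the 4 pairs gave p = 0.125, the smallest that 4 pairs allow. The labels do not say which part of the gene was altered, so a probe outside it checks neither the labels nor the direction. If the alteration lowered the RNA that this probe reads, the higher value would go against the direction assumed here. Which case holds was not tested.

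The lowest values in the mutant belonged to secreted proteins of the acute phase response. Saa1 and Saa2, serum amyloid A proteins, had mean log2 ratios of -4.40 ± 0.46 and -5.29 ± 0.70 (SD, n = 4). Lcn2, the siderophore-binding protein lipocalin 2, was at -5.05 ± 1.42, and each of these was lower in 4 of 4 pairs. Sqle, a cholesterol synthesis enzyme, was at -1.35 ± 0.24, and Ppp1r3b, a glycogen-targeting subunit of protein phosphatase 1, at -1.68 ± 0.35. The remaining leading probes on this side were Nucb2 at -2.22 ± 0.79, D14Ertd449e (now Tmem254a) at -1.37 ± 0.15, Btg3 at -1.31 ± 0.18, Dynll1 at -1.27 ± 0.15 and Fndc3b at -1.20 ± 0.15. Probes for Saa1 and Saa2 may cross-hybridise, because the genes are nearly identical.

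On the higher side, Mtmr7, a myotubularin-related protein, had a mean log2 ratio of 1.76 ± 0.37 (SD, n = 4), and Rundc3a was at 1.69 ± 0.64. The other 8 leading probes were those for Mmp1a, Zfp7, BC053393, Tbx10, 5830411N06Rik, Efcab5, Spesp1 and Taar9, with means from 1.09 for Efcab5 to 1.97 for Zfp7. In 9 of these 10 genes both pairs with the mutant in Cy3 lay above both pairs with the mutant in Cy5, and 7 of the 10 were dimmer than the median named probe. Among the 10 leading lower genes these numbers were 1 and 0.

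None of these values passed the test over all probes. With limma and a dye term, 0 of 40238 probes passed an adjusted p of 0.05, and 2673 had an unadjusted p under 0.05 where 2012 would be expected by chance. The fit without the dye term gave 0 and 2328, and the unmoderated one-sample test gave 0. In simulated data with the same spread, 0% of 50 probes changed by 1 log2 unit were called, 2% at 2 units, 48% at 4 units and 78% at 6 units. A fit in which the prior variance followed probe intensity, chosen after the count of 0 was seen, called 42 of 20379 named probes, 14 higher and 28 lower, among them all 10 leading lower genes and 2 of the 10 leading higher ones, Mtmr7 and Zfp7. With no dye term the gene Zfp7 lost that call (adjusted p = 0.405, against 0.0432), while the gene Mtmr7 had an adjusted p of 0.0283.

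Acute phase genes fell as a list. Of 31 measured members, 29 had a negative mean and 24 were lower in 4 of 4 pairs, with a median log2 ratio of -0.95. Apcs, serum amyloid P component, was at -2.13 ± 0.66 (SD, n = 4), beside Saa1, Saa2 and Lcn2 above. The list passed camera with the preset correlation (adjusted p = 4.76e-14), but not with an estimated one (adjusted p = 0.786 with an estimated correlation). The estimated correlation between its genes was 0.58, and a sign-flip test of the 4 pairs gave p = 0.125. Adjusted over the list alone, 14 members passed, 13 lower and 1 higher, against 0 over all probes. The higher one was Hamp2, a hepcidin gene, at 2.04 ± 0.81, singled out after its value was seen. Pair medians ran from -1.84 in pair 3 to -0.20 in pair 4, and the list median was -0.60 without pair 3 and -1.46 without pair 4. Macrophage markers had a median of 0.63, with -0.20 in pair 3 and 1.00 in pair 4.

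Cholesterol synthesis genes also fell. Of 24 members, 23 had a negative mean and 17 were lower in 4 of 4 pairs, with a median log2 ratio of -0.69. Dhcr7, the last reductase of the pathway, was at -1.07 ± 0.32 (SD, n = 4), and Insig1, a sterol-responsive regulator, at -0.96 ± 0.23. The list passed camera with the preset correlation (adjusted p = 2.84e-12), with adjusted p = 0.786 with an estimated correlation. That correlation was estimated at 0.38, and a sign-flip test of the 4 pairs gave p = 0.125. Adjusted over the list alone, 11 members passed, all of them lower, against 0 over all probes.

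PPAR alpha targets, genes of fatty acid oxidation and ketone synthesis, rose. Of 34 members, 32 had a positive mean and 14 were higher in 4 of 4 pairs, with a median log2 ratio of 0.56. Angptl4, an inhibitor of lipoprotein lipase, was at 1.34 ± 0.67 (SD, n = 4), the lipid droplet protein gene Cidec at 1.20 ± 0.55 and Aldh3a2 at 0.95 ± 0.42. Cidec is also in the adipocyte marker list, which had a median of 0.26 and did not pass. The adjusted p was 9.27e-08 with the preset correlation, and adjusted p = 0.786 with an estimated correlation. Adjusted over the list alone, 0 members passed.

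**Figure D1:**
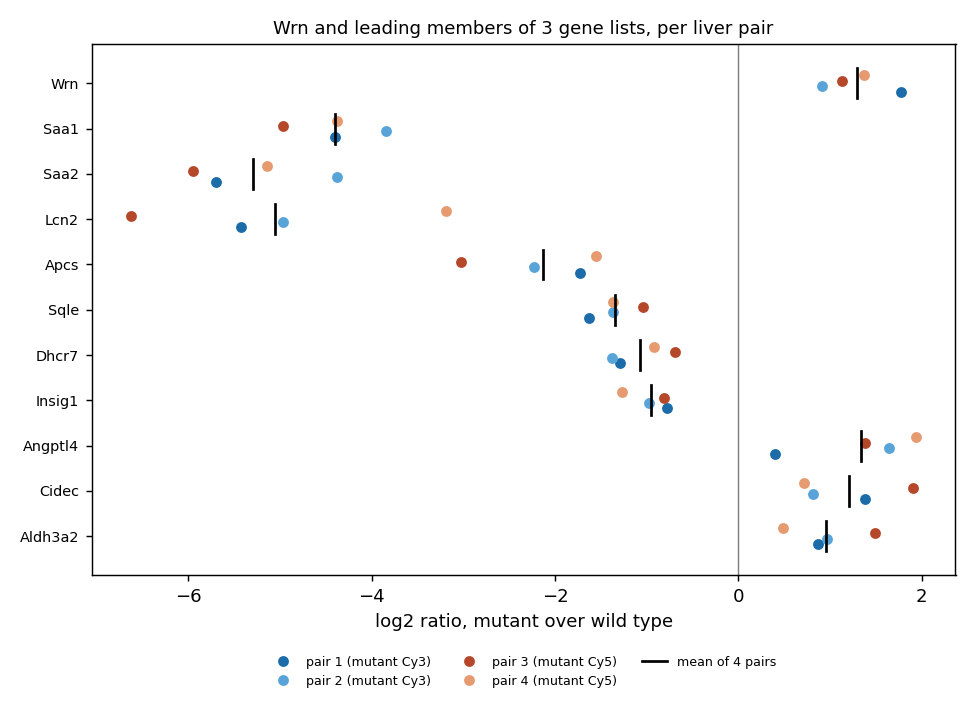
Log2 ratio of mutant over wild type (horizontal axis) for Wrn and leading members of the acute phase, cholesterol synthesis and PPAR alpha lists (vertical axis). Points are the 4 liver pairs, coloured by the dye of the mutant, and bars are means. Saa1 lay between -4.97 and -3.85 in the 4 pairs.

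Fatty acid synthesis genes fell as a list, with a negative mean in 21 of 24 genes, a median log2 ratio of -0.38 and an adjusted p of 0.00467 with the preset correlation (adjusted p = 0.786 with an estimated correlation). The call depended on pair 4. Its median was -1.58, against -0.37, -0.38 and 0.26 in pairs 1 to 3. Without pair 4 the list median was 0.015 and the call was lost (adjusted p = 0.925). In that fit pair 3 counted as much as pairs 1 and 2 together, which drew the list median toward the value of pair 3. The call was also lost without pair 2 (adjusted p = 0.0521), and without pair 3 the median was -0.71. Acacb, a source of malonyl-CoA, was at -1.33 ± 0.97 (SD, n = 4), Lpin1 at -0.90 ± 0.81 and Srebf1 at -0.34 ± 0.16. Acacb was at -0.77 without pair 4, and Lpin1 at -0.52 without pair 3. In these fits pair 3 for Acacb, at -0.40, and pair 4 for Lpin1, at 0.31, counted as much as pairs 1 and 2 together.

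Endoplasmic reticulum stress genes fell, with a negative mean in 19 of 26 genes, a median log2 ratio of -0.32 and an adjusted p of 0.00243 (adjusted p = 0.786 with an estimated correlation). The chaperone genes Pdia6 and Hyou1 were at -0.92 ± 0.58 and -0.55 ± 0.55 (SD, n = 4), Asns at -0.64 ± 0.28 and Eif2ak3 at -0.44 ± 0.45. The call was lost without pair 3, with a median of -0.19 and an adjusted p of 0.136. Proteasome subunits fell by a smaller margin, with a negative mean in 24 of 30 genes and a median of -0.091 (adjusted p = 0.0342, and adjusted p = 0.786 with an estimated correlation). Psma3, Psmd13, Psmd7 and Psmc5 led that list at -0.55 ± 0.89, -0.47 ± 0.42, -0.32 ± 0.18 and -0.34 ± 0.28. Psma3 was at -0.35 without pair 3, a fit in which pair 4, at 0.53, counted as much as pairs 1 and 2 together. The proteasome call was lost without pair 1, 3 or 4, with adjusted p up to 0.289. The median was -0.021 without pair 1 and -0.15 without pair 2. Insulin and IGF signalling genes rose, with a positive mean in 17 of 21 genes and a median of 0.31 (adjusted p = 0.0143, and adjusted p = 0.786 with an estimated correlation). Klf10, Igfbp3, Sirt3 and Ghr led it at 0.78 ± 0.28, 0.57 ± 0.13, 0.55 ± 0.17 and 0.49 ± 0.19, and the call was lost without pair 1 or 4, with medians of 0.12 and 0.17 and adjusted p up to 0.311. Adjusted over the list alone, 0 members of these lists and of the fatty acid synthesis list passed.

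Markers of 4 cell types passed the same test. Kupffer cell and macrophage markers rose, with a positive mean in 16 of 16 genes and a median log2 ratio of 0.63 (adjusted p = 2.23e-06, and adjusted p = 0.786 with an estimated correlation). Their correlation was estimated at 0.70, and a sign-flip test of the 4 pairs gave p = 0.25. Vsig4, Csf1r, Cybb and Lyz2 led them at 0.84 ± 0.37, 0.92 ± 0.54, 1.08 ± 0.85 and 0.62 ± 0.61 (SD, n = 4), and without pair 4 Csf1r was at 0.60 and Lyz2 at 0.41. In this list pair 3 had a median of -0.20 and the list median without pair 4 was 0.36. B cell and plasma cell markers rose with a positive mean in 8 of 10 genes and a median of 0.59 (adjusted p = 0.0181, and adjusted p = 0.786 with an estimated correlation), led by Cd79b at 0.87 ± 0.16 (SD, n = 4), 2010001M09Rik (now Mzb1) at 0.91 ± 0.65, Cd74 at 1.08 ± 1.03 and Igj (now Jchain) at 0.91 ± 1.16. Cd74 and Igj were negative in pair 3, and without 1 pair Cd74 ran from 0.51 (pair 4 left out) to 1.65 (pair 3) and Igj from 0.41 (pair 1) to 1.40 (pair 2). Sinusoidal endothelial markers rose with a positive mean in 12 of 14 genes and a median of 0.32 (adjusted p = 0.0143, and adjusted p = 0.786 with an estimated correlation), led by Ptprb, Fcgr2b, Oit3 and Bmp2 at 0.65 ± 0.17, 0.55 ± 0.21, 0.54 ± 0.21 and 0.53 ± 0.24. Cholangiocyte markers fell with a negative mean in 9 of 11 genes and a median of -0.42 (adjusted p = 0.0143, and adjusted p = 0.786 with an estimated correlation), led by Krt19, Sox9, Muc1 and Cftr at -1.12 ± 1.12, -0.53 ± 0.25, -0.50 ± 0.22 and -0.47 ± 0.20. The authors' deposited table gives Cftr the opposite sign, at 0.76. The B cell call was lost without pair 4 (adjusted p = 0.127) and among probes brighter than the median (median 0.29, adjusted p = 0.222), and the endothelial and cholangiocyte calls without pair 1, 2 or 3 (adjusted p up to 0.134 and 0.136), with a cholangiocyte median of -0.27 without pair 3. Adjusted over the list alone, 0 members of these 4 lists passed.

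**Figure D2:**
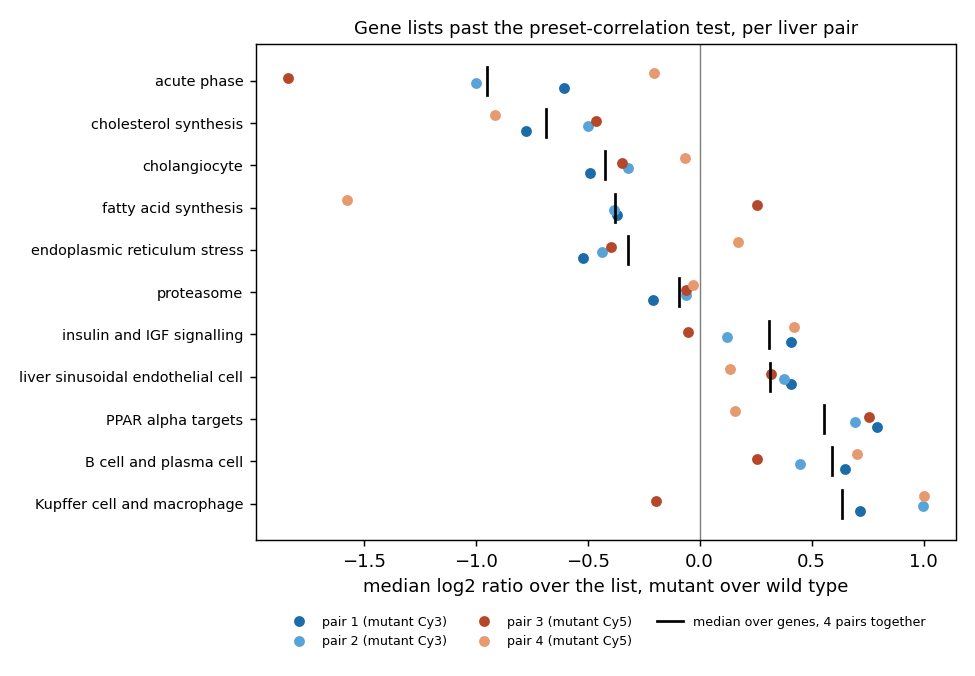
Median log2 ratio of mutant over wild type (horizontal axis) for the 11 lists that passed camera with the preset correlation (vertical axis), all with adjusted p = 0.786 with an estimated correlation. Points are the 4 liver pairs, coloured by the dye of the mutant, and bars are medians over genes of the fitted mean. Cholesterol synthesis lay below 0 in each pair, from -0.91 to -0.46, while Kupffer cell markers had 1 pair at -0.20.

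Genes tied to the helicase itself did not pass camera as lists. RecQ helicases and their partners had a median log2 ratio of 0.044 over 19 genes, DNA repair genes -0.12 over 25, p53 targets -0.057 over 20, and senescence genes 0.33 over 17. The DNA repair and p53 lists had positive means, 0.019 and 0.014, against negative medians and a test direction of lower. Vitamin C synthesis and transport genes had a median of 0.11 over 15 genes, and Gulo, the last enzyme of ascorbate synthesis, was at 0.13 ± 0.49 (SD, n = 4), singled out after the data were seen. NRF2 and glutathione genes were at 0.12, reactive oxygen scavenging genes at 0.052 with a mean of -0.26 and a test direction of lower, oxidative phosphorylation genes at 0.12, TCA cycle genes at -0.016 and heat shock genes at 0.071 with a mean of -0.0019 and a test direction of lower. With fry's test for change in either direction, which does not compare a list with other genes, p53 targets (adjusted p = 0.0397), vitamin C genes (0.00968), TCA cycle genes (0.00206) and heat shock genes (0.0254) passed. The lowest adjusted p among all 37 lists that did not pass camera was 0.0757, for oxidative phosphorylation, and 0 of their members passed over all probes. Oxidative phosphorylation passed without pair 1 (median 0.20, adjusted p = 0.0437) and with intensity above the median (adjusted p = 0.0379), and NRF2 genes without pair 4 (median 0.19, adjusted p = 0.0257). Over their alternatives the adjusted p of both ran up to 0.786.

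The dye coefficient compares the pairs of opposite dye orientation, which came from different animals. It therefore mixes labelling with differences between those animals and cannot be read as labelling alone. This coefficient passed at 0 of 40238 probes with limma, with 2685 at an unadjusted p under 0.05. Over all probes the mean correlation between arrays was 0.093 for the same dye orientation and -0.025 for opposite orientations. After the dye term was removed, arrays of opposite orientation correlated at 0.35 to 0.42 and those of the same orientation at -0.28 and -0.20, signs that the removal itself builds in. Among named probes brighter than the median, all 6 correlations were positive, from 0.15 to 0.37. These are correlations across probes, which are not independent replicates.

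The authors' deposited table lists 20909 genes, of which 1720 had an unadjusted p under 0.05, 871 higher and 849 lower, and 340 a p under 0.01. After Benjamini-Hochberg adjustment of the authors' deposited p-values, 0 passed 0.05 and the lowest adjusted value was 0.0906. Of 17686 genes with 4 values, 17537 had a fold change in the authors' deposited table equal to the mean of the 4 arrays within 1e-04, and 149 differed by more. Among the latter were 4 genes named above, for which the authors' deposited table gives log2 fold changes of -0.76 for Sox9, 0.76 for Bmp2 and 0.62 for Fcgr2b, besides Cftr. The cause of these differences is not given in the sources used here.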

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

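The tests of explanations below, and the sign patterns with a prior following intensity, were chosen after the results they concern had been seen. Of 112 results examined for a pair far from the other 3, 6 had one, where chance gives about 5.6.

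Pair 1 had 3547 missing values, against 1070 to 1195 in the others. The median log2 ratio of PPAR alpha targets was 0.16 in pair 4, against 0.69 to 0.79. Lpin1 was at 0.31 in pair 4, against -1.46 to -1.20. DNA repair genes had a median of -0.22 in pair 1, against -0.043 to -0.026. Bile acid genes had a median of 0.19 in pair 2, against 0.052 to 0.055, and hypoxia genes -0.15 in pair 1, against 0.083 to 0.13.

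The median of the acute phase list was below 0 in each pair. Dye bias would turn the sign between orientations once arrays share 1 direction, but the orientation median nearer 0 was -0.88. That premise was taken from how the authors averaged the arrays and was not tested. Fewer hepatocytes would lower hepatocyte markers as much, but their median was -0.15, with Fgb in both lists. Inflammation in a single wild-type animal would end the pattern without its pair, but the median stayed at -0.60 or lower. A difference in health or housing shared by all animals of a genotype stays open, as does the genotype itself, and neither was tested.

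The median of the cholesterol synthesis list was below 0 in each pair. If the arrays share 1 direction, dye bias is argued against by an orientation median of -0.66. A different clock phase of the mutants at sampling was not decided: clock output genes exceeded clock activators by 0.91 ± 0.79 (SD, n = 4) on the log2 scale, by 1.62, 0.32, 0.15 and 1.56 in pairs 1 to 4. In pair 3 both sets were lower in the mutant, at -0.15 and -0.30, and the genes of this index were picked after the clock values were seen, so it supports nothing. A longer time without food could lower these genes with fatty acid synthesis genes, whose median of -0.38 lay within the spread of its pairs. It could also raise PPAR alpha targets, of which 32 of 34 had a positive mean, with pair medians from 0.16 to 0.79. A longer time without food cannot be told apart from genotype. An effect of genotype stays open and untested.

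The Wrn probe was higher in both orientations, with the mean nearer 0 at 1.25, which argues against dye bias if the arrays share 1 direction. Whether the numerator is wild type, and where the probe lies in the gene, were not tested.

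With 4 pairs there are only 8 sign patterns, too few for a share under 0.05. Without a dye term the real pattern gave 2328 probes at an unadjusted p under 0.05, and the highest other pattern gave 2375, so 2 of the 8 were as large. That other pattern follows dye orientation, and with the dye term the real count was 2673 and that of the dye coefficient 2685. With a prior following intensity the real pattern called 40 named probes and the highest other 0, so 1 of 8 was as large. For lists the real pattern gave 11 and the highest other 6, again 1 of 8, and the dye pattern gave 0.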

How the results depend on the processing

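Settings that follow or filter on intensity beyond the planned median filter, combinations with no dye term, and the fit of complete probes were chosen after the data were seen. The count of 0 probes stayed 0 under centring, scaling, each pair left out, array weights, robust eBayes, named probes only, no dye term, the opposite reading of the dye swap, both other thresholds, the unmoderated test and complete probes. It became 1 with intensity above the median, and 2 with that filter and no dye term. Above intensity 8 it was 2, and 124 with no dye term. Above intensity 9 it was 11, and 161 with no dye term. With a prior following intensity it was 42, and 40 with no dye term, and with the median filter added it was 44, and 100 with no dye term. These counts span 0 to 44 with the dye term and 0 to 161 with none, so the number of called genes depends both on how dim probes are treated and on the dye term. Dim probes varied more: the median SD was 0.88 in the dimmest part of the named probes and 0.27 in the brightest. The Wrn transcript value of 1.29 passed in 3 settings, each added and with no dye term (adjusted p from 0.0256 to 0.0423), and missed in the rest, and its range without 1 pair was 1.08 to 1.51. The dye count was 0 wherever it was run. Array weights were 1.01 for pairs 1 and 2 and 0.993 for pairs 3 and 4. With the dye term, arrays of the same orientation get the same weight, so this setting could not downweight a single array.

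The 11 list calls became 0 with an estimated correlation, a test on 2 residual degrees of freedom, and 0 with fry. Without 1 pair, 7 or 8 of the 11 were kept: 4, 3, 4 and 4 were lost without pairs 1 to 4. In the same fits 1, 0, 2 and 4 other lists gained a call, for totals of 8 to 11. Acute phase, cholesterol synthesis, PPAR alpha and Kupffer lists kept their calls whichever pair was left out. Robust eBayes and the restriction to named probes for lists, gene means over probes, the choice of the least variable or brightest probe of a gene, and a second set of per-array values were not run, having nothing to act on. The mean correlation between arrays moved from 0.0145 to 0.22 for bright probes.

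Some lists changed the direction of their test, none of them past the threshold there, and the cause was not tested. Their medians without 1 pair ran from -0.71 to 0.015 for fatty acid synthesis, -0.048 to 0.086 for periportal, -0.21 to 0.13 for neutrophil, -0.022 to 0.15 for vitamin C, 0.021 to 0.094 for heat shock, -0.065 to 0.25 for fibrosis, 0.014 to 0.059 for hypoxia, -0.23 to 0.069 for interferon, -0.086 to 0.032 for ribosomal, -0.029 to 0.056 for TCA cycle and 0.055 to 0.12 for bile acid genes. With intensity above the median they were -0.056 for fibrosis, 0.37 for neutrophil, 0.26 for acinar, -0.20 for gallbladder and 0.066 for sex chromosome genes. With no dye term they were 0.071 for heat shock and 0.0062 for hypoxia, and 0.071 for heat shock with fry.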

Other observations

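The choice of genes and probes singled out below was made after their values were seen, while the lists and their tests were planned.

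Clock genes were not called as a list by camera, with a median log2 ratio of 0.26 over 29 genes, though the call appeared without pair 3 (adjusted p = 0.0327) and with intensity above the median (adjusted p = 0.0417). Over the alternatives tried for the circadian clock list the adjusted p ran from 0.0327 to 0.822. Dbp, a clock output gene, was at 0.99 ± 0.31 and Per1 at 1.04 ± 0.62 (SD, n = 4), while Arntl, which encodes BMAL1, was at -0.76 ± 0.78 and Clock at -0.46 ± 0.30. None of these passed over all probes.

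Other metabolic lists did not pass camera, though fry's test for change in either direction passed those for gluconeogenesis, xenobiotic metabolism, urea cycle and lipoproteins. Median log2 ratios were 0.21 for gluconeogenesis and glycogen, -0.18 for glycolysis and pentose phosphate, 0.10 for urea cycle and amino acids, 0.13 for xenobiotic metabolism, 0.11 for bile acids and -0.0053 for lipoproteins, whose mean was 0.038 with a test direction of higher. Male-biased liver genes had a median of -0.19 and female-biased ones 0.36. Inflammation genes were at 0.24, interferon-stimulated genes at -0.021, cell cycle genes at -0.19, fibrosis and matrix genes at 0.17, hypoxia genes at 0.0062 and ribosomal proteins at -0.032. Without 1 pair some of these lists passed: glycolysis without pair 3 (median -0.21, adjusted p = 0.0107), and without pair 4 female-biased genes (0.45, adjusted p = 0.0135) and interferon-stimulated genes (-0.23, adjusted p = 0.00106). Over all alternatives their adjusted p ran up to 0.786, 0.805 and 0.92. In the glycogen list adjusted over the list alone, Ppp1r3b at -1.68 and Gys2, liver glycogen synthase, at 1.00 ± 0.34 (SD, n = 4) passed.

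Among cell type markers that did not pass camera, medians were -0.15 for hepatocytes, 0.15 for pericentral and 0.056 for periportal hepatocytes, -0.034 for neutrophils with a mean of -0.42, 0.33 for T and NK cells, 0.42 for stellate cells, 0.46 for erythroid cells, -0.11 for pancreatic acinar cells, 0.26 for adipocytes, -0.13 for muscle with a mean of 0.018, -0.18 for gallbladder and intestine and -0.10 for sex chromosome genes. Fry's test for change in either direction passed the erythroid, stellate, muscle, acinar, pericentral, periportal, neutrophil and sex chromosome lists. The periportal list had a mean of -0.036 and a test direction of lower. When adjusted over the list alone, Oat at 1.25 ± 0.39 passed among pericentral markers, Cdh1 at -0.97 ± 0.15 among periportal ones and Lcn2 among neutrophil ones (SD, n = 4). The adipocyte list passed without pair 4 (median 0.46, adjusted p = 0.0433), with adjusted p up to 0.786 over its alternatives. The neutrophil list holds Lcn2, which is also an acute phase member.

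Of the probes unnamed here, A_52_P318673 and A_52_P517668 had mean log2 ratios of -4.28 ± 0.90 and -3.34 ± 0.82, and A_52_P739530 and A_52_P1101227 had 1.60 ± 0.44 and 1.03 ± 0.54 (SD, n = 4), each in the same direction in 4 of 4 pairs. None passed over all probes (adjusted p = 0.736).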
